A study of Mus musculus with 8 samples.

How the data were processed

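Bulk RNA sequencing was made from mouse bone marrow-derived macrophages (BMDMs), cells isolated from bone marrow and cultured into macrophages. Per the labels, 4 groups were used. Control cells received neither stimulus. LPS cells received lipopolysaccharide (LPS), a bacterial cell wall component that signals through Tlr4, at 100 ng/ml for 4 h. IL-4 cells received interleukin 4, a cytokine of type 2 immunity, at 20 ng/ml for 24 h. Cells of the group called IL-4 then LPS received 20 ng/ml IL-4 for 24 h, were washed, and then received 100 ng/ml LPS for 4 h. Whether the cells of the IL-4 group were also washed and kept for a further 4 h is not given in the sources used here. Each group held 2 libraries, numbered 1 and 3 in the labels. RNA was extracted with Trizol and libraries were prepared by standard Illumina protocols, per the labels' protocols.

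The deposited table holds raw read counts, whole numbers for 54532 genes named by Ensembl identifier, with the start and end of each gene in base pairs. Per the submitters' processing notes, HISAT2, StringTie and HTSeq were used with the mm10 mouse genome, and no versions were given. Strandedness, read length and the treatment of reads that match several genes were not given in the sources used here. Reads of overlapping or antisense genes could therefore not be told apart, and counts of near-identical copies are uncertain. This applies to Chil3 beside Chil4, Mgl2 beside Clec10a, Rnase2a beside the other genes of its eosinophil-associated family, Ifi205 beside related Ifi200 genes, Serpina3f beside its Serpina3 neighbours, and the MHC genes. Coordinates were compared with GENCODE M21, where 54409 of the identifiers were found and 53499 had the same start and end. The table holds 6 further count columns that the labels do not describe, and these were not used here. Gene symbols were taken from the deposited table, in which 103 symbols stand for more than 1 gene.

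Counts per library totalled 7924932 to 9431852, and tested genes held 99.84% to 99.92% of them. Folds against a group without a read were computed against a floor of 3 reads over the group's 2 libraries. Where a group held 1 to 3 reads, the ratio is given with an exact conditional binomial (Clopper-Pearson) 95% interval. No fold was given where both groups held 3 reads or fewer. Reads carried no molecular identifiers, so intervals and floors cover counting error only.

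Genes were kept by edgeR's filterByExpr with the group as argument, which left 12234 genes, 11145 of them protein-coding. A further 33464 genes held no read in the 8 libraries. Libraries were scaled with trimmed mean of M-values (TMM) factors, which ran from 0.786 to 1.252. Levels are given as CPM, the usual count unit scaled by these library totals. Adjusted p-values for genes come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over all 12234 genes, with 1 mean per group and a spread shared by all 8 libraries (4 residual degrees of freedom, 3.78 prior degrees of freedom, common dispersion 0.0402). A gene was called at an adjusted p under 0.05, and calls with an absolute log2 fold change of at least 1 were also counted. Fold changes are given on the log2 scale with their standard error (SE), and levels as mean ± SD with n = 2. The SE was computed from the test, as the absolute log2 fold change divided by the square root of the F statistic. It is therefore approximate, above all for genes with few reads. The p-values measure the spread between 2 libraries per group. The labels do not say what the libraries of a group are, but their sex chromosome reads, given below, show cells of different sex, so this spread holds a difference between animals as well as technical variation. Whether libraries with the same number share an animal or a culture is not given in the sources used here.

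5 comparisons were made: LPS against control, IL-4 against control, IL-4 then LPS against LPS alone, IL-4 then LPS against IL-4 alone, and the difference between the LPS responses with and without prior IL-4. LPS-induced genes were defined by the average LPS effect over both arms (adjusted p under 0.05, log2 fold change of at least 1), a contrast independent of IL-4 then LPS against LPS alone. LPS-reduced genes were defined alike with a log2 fold change of -1 or less. Effects were also correlated across genes, without p-values because genes are not independent replicates. The pairs of effects correlated share no library.

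27 gene lists were tested with limma's camera at a preset correlation between genes of 0.01, adjusted by the Benjamini-Hochberg method over the lists of a comparison, and again with a correlation estimated from the data. The lists covered IL-4 and alternative activation genes, inflammatory cytokines, chemokines, anti-inflammatory and feedback genes, NF-kB subunits with immediate inflammatory effectors, the type I interferon response, and pattern recognition with the inflammasome. Others covered glycolysis, the tricarboxylic acid cycle, oxidative phosphorylation, fatty acid oxidation, cholesterol synthesis, cholesterol efflux with lipid handling, the cell cycle, MHC class II with co-stimulation, MHC class I presentation, phagocytic and scavenger receptors, the unfolded protein response, and macrophage identity. Marker lists of neutrophils and granulocyte precursors, lymphocytes, erythroid cells, dendritic cells, mast cells with basophils and eosinophils, and stromal cells stood for other cells that a bone marrow culture can hold. Mitochondrially encoded transcripts and ribosomal proteins were the remaining lists. A list needed at least 3 tested members.

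The groups, the 5 comparisons, the tests, the lists and the rule for naming genes were chosen before the data were examined. Named genes were, per comparison, the 5 largest increases and 5 largest decreases among called protein-coding genes with a mean log2 CPM of at least 2 and no overlap between the groups' libraries. Up to 4 called members of each list described were added, or up to 2 where none passed. Il4ra, Arg1, Retnla, Chil3, Mrc1, Tnf, Il6, Il1b, Il12b, Il10, Ifnb1, Nos2, Cxcl10, Tlr4 and Cd14 were named whatever their result, except where both sides of a fold lay at the floor. Applying the same rule to the fit with a replicate term was added after the data were seen. A gene that met these rules is not reported here.

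Replicate numbers 1 and 3 recur in all 4 groups, and the labels do not say what they mark. In the data, libraries with the same number deviated together from their group means, with correlations across genes of 0.34 to 0.52 over the 6 pairs of groups. Libraries numbered 1 held 2936 to 4465 reads of Xist, the RNA of the inactive X chromosome, and those numbered 3 held 0. Reads of Y chromosome genes numbered 50 to 134 and 1316 to 1573. The number therefore separates the libraries by sex in every group and was treated as a batch. The fit with the replicate number as an added term, called the replicate block or replicate term, was planned as an alternative. Its values stand beside the others where they changed a reported call or moved a reported count of called genes by more than 1.5 times. It has 3 residual degrees of freedom, 5.9 prior degrees of freedom and a common dispersion of 0.0133.

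Both fits were tested on simulated counts with 67, 67 and 66 genes changed 1.5-fold, 2-fold and 4-fold. The counts were drawn from the fit with the replicate term, with its dispersions and a replicate effect shared by all 4 groups. The higher recovery with the block was therefore partly built in. In the data the replicate effect differed between groups for some genes, such as the interferon response genes described below. For IL-4 against control, the fit without the term recovered 0%, 14.9% and 68.2% of them, with 0 false among 55 calls, and the replicate block recovered 23.9%, 61.2% and 93.9%, with 8 false among 127 calls. For IL-4 then LPS against LPS alone, the shares were 0%, 7.5% and 63.6% (0 false of 47) against 31.3%, 67.2% and 84.8% (22 false of 144). For the difference of responses they were 0%, 0% and 36.4% (0 false of 24) against 10.4%, 31.3% and 74.2% (17 false of 94). For LPS against control, 62.1% of genes changed 4-fold were recovered (0 false of 58), and with the block 83.3% (19 false of 141). For IL-4 then LPS against IL-4 alone, 66.7% of such genes were recovered (0 false of 52), and with the block 83.3% (3 false of 105). With the block, the share of false calls was above the threshold of 0.05 in every comparison except IL-4 then LPS against IL-4 alone. Calls made with the replicate block alone are therefore less strict, and their adjusted p may understate the share of false calls. In a simulation of IL-4 then LPS against LPS alone, a raised list gave a camera p of 6.42e-36, and 4 of 200 random lists had an unadjusted p under 0.05. The simulated genes were drawn independently of each other, so this does not test the preset correlation for lists whose genes vary together.

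The alternatives were RLE, upper-quartile and library-size scaling, the DESeq2 Wald test, no low-count filter, a filter of at least 1 CPM in 2 libraries, a fit of the compared groups alone, the replicate block, and each library left out in turn. When a library is left out, the remaining library of its group is assumed to vary like the other groups. DESeq2 with the replicate block, the replicate block without X and Y genes, and the list tests with both an estimated correlation and the replicate block were chosen after seeing the data. R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0 were used, with Python 3.11.15 and matplotlib 3.10.9 for the plots.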

Results

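Transcript levels were measured by RNA sequencing in mouse bone marrow-derived macrophages at rest, after 4 h of LPS, after 24 h of IL-4, and after 24 h of IL-4, a wash and 4 h of LPS. Each of the 4 groups held 2 libraries, called replicates 1 and 3 as in the labels. Control libraries held 9247019 and 8480057 counts, LPS libraries 8689368 and 9212153, IL-4 libraries 9006361 and 9422396, and libraries of IL-4 then LPS 7924932 and 9431852. The title of the series names IL-4 as an inducer of a form of trained immunity, in which an earlier stimulus alters the response to a later one. The first principal component of the tested genes held 78.5% of the variance and separated libraries with and without LPS. The second held 7.8% and separated replicate 1 from replicate 3, and the third held 5.8% and separated libraries with and without IL-4. Mitochondrial transcripts made up 1.07% to 1.61% of counts.

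The first comparison, LPS against control, asked how macrophages without IL-4 responded to LPS. Genes of inflammation and of interferon signalling rose. Nos2, the inducible nitric oxide synthase (ENSMUSG00000020826, chromosome 11, 78920787 to 78960254, mm10), rose from 1.16 ± 0.175 CPM to 1626 ± 408 CPM (mean ± SD, n = 2), a log2 fold change of 10.44 ± 0.35 (SE). Il1b, the precursor of the cytokine interleukin 1 beta (ENSMUSG00000027398, chromosome 2, 129364570 to 129371139), rose from 1.93 ± 1.06 CPM to 1187 ± 238 CPM, and Tnf, tumour necrosis factor, from 29.9 ± 28.1 CPM to 2440 ± 1269 CPM (log2 fold change 6.36 ± 1.06). Il6 and Il12b, which encode interleukin 6 and the shared subunit of interleukins of the IL-12 family, held 1 read each in the control libraries. Il6 was 10520-fold (95% counting interval 1888 to 415600) higher after LPS, and Il12b 12210-fold (95% counting interval 2190 to 482300) higher. Cx3cr1, the receptor of fractalkine, fell by 4.48 on the log2 scale, from 31.5 ± 14.1 CPM to 1.39 ± 0.0129 CPM.

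Of the largest increases, Edn1, the precursor of the vasoconstrictor endothelin 1, was 4408-fold (95% counting interval 791 to 174200) higher after LPS. The serpin Serpina3f was at least 220-fold higher and Il12a, the specific subunit of interleukin 12, at least 155-fold higher. Of the largest decreases, Galnt9, a glycosyltransferase, was at least 19.9-fold lower. The zinc finger gene Zfp395 was 297-fold (95% counting interval 53.0 to 11740) lower and Gpr183, an oxysterol receptor, 97.8-fold (95% counting interval 33.2 to 476) lower. Bmf, a pro-apoptotic BH3-only gene, had a log2 fold change of -7.08 ± 0.41, and Cnr2, cannabinoid receptor 2, of -6.91 ± 0.35. Among genes followed in every comparison, Il10, an anti-inflammatory cytokine, rose by 6.01 ± 1.12 on the log2 scale and Cd14, a co-receptor for LPS, by 2.49 ± 0.19. Ifnb1, interferon beta, held 2 reads in control and 55 after LPS, a ratio of 41.4 (95% counting interval 10.9 to 350.7). The chemokine gene Cxcl10 rose by 8.92 ± 1.02. The mannose receptor Mrc1 (0.56 ± 0.56, adjusted p 0.451), the IL-4 receptor subunit Il4ra (1.48 ± 0.62, 0.094), Chil3 (-0.40 ± 0.45, 0.505) and the LPS receptor Tlr4 (-0.17 ± 0.19, 0.5) did not pass. With the replicate term, Mrc1 (adjusted p 0.0187) and Il4ra (0.0142) passed. Mrc1 turned negative without LPS replicate 1, at -0.31, and with library-size scaling, at -0.03. Retnla held 0 reads and Arg1 at most 1 read in both groups.

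Among the gene lists, 41 of 41 type I interferon response genes rose, with a median log2 fold change of 5.05. Examples were Ifi205 (8.39 ± 0.56), the guanylate-binding protein gene Gbp5 (7.91 ± 1.02), the antiviral gene Rsad2 (7.36 ± 0.85) and the immunity-related GTPase gene Iigp1 (7.29 ± 0.74). All 16 tested chemokines rose, among them Cxcl11, which had 2 reads in control and was 448-fold (95% counting interval 123 to 3703) higher, Ccl7 (7.998 ± 0.64) and Cxcl3 (7.93 ± 0.62). Of 18 inflammatory cytokines, 15 rose, 0 fell and 3 did not pass. Il1a, interleukin 1 alpha, rose by 9.57 ± 0.59. Of 21 NF-kB subunits and effectors, 20 rose, including Ptgs2, the inducible cyclooxygenase (10.39 ± 0.41), Cd40 (7.69 ± 0.73) and the siderophore-binding Lcn2 (3 control reads, 256-fold (95% counting interval 87.2 to 1246) higher). Of 17 MHC class I presentation genes, 16 rose, including the peptide transporter Tap1 (3.82 ± 0.36) and the transactivator Nlrc5 (3.79 ± 0.24). Of 22 anti-inflammatory and feedback genes, 17 rose and 1 fell, among them the cytokine signalling inhibitors Socs3 (7.42 ± 0.53) and Socs1 (6.63 ± 0.49) and the NF-kB regulator Nfkbiz (5.97 ± 0.82). Of 29 pattern recognition and inflammasome genes, 19 rose and 5 fell. The sensors Nod1 (4.64 ± 0.25) and Tlr3 (4.11 ± 0.21) were among those that rose. Adjusted over the list alone, 41, 16, 16, 21, 16, 17 and 19 genes of these lists rose, in the order given. With genes at the read floor set to it, the medians were 5 for interferon genes, 7.26 for chemokines (otherwise 7.28) and 5.06 for cytokines (otherwise 5.77).

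Of 36 cell cycle genes, 19 fell and 3 rose (20 and 3 adjusted over the list alone, 24 and 5 with the replicate term), with a median of -1.31. The centromere gene Cenpf (-2.89 ± 0.55), the ribonucleotide reductase subunit Rrm2 (-2.72 ± 0.33) and the mitotic activator Cdc20 (-2.61 ± 0.32) fell, and Ccne1, cyclin E1, rose (2.88 ± 0.34). Of 20 glycolysis genes, 8 rose and 12 did not pass (8 adjusted over the list alone, and with the term 9 rose and 1 fell), including Pfkfb3 (3.81 ± 0.72), Pfkp (2.04 ± 0.13) and the hexokinase Hk2 (1.62 ± 0.23). Camera's call of the glycolysis list ended with an estimated correlation (adjusted p 0.703), and also without control replicate 3 or LPS replicate 1. With library-size scaling the median of this list, 0.41, was -0.20, and 7 and 6 members rose and fell. Of 27 IL-4 and alternative activation genes, 9 rose and 4 fell (9 and 4 adjusted over the list alone, 14 and 4 with the term), with a median of 0.84. Of 20 macrophage identity genes, 5 rose and 5 fell (7 and 5, and 8 and 6 with the term), among them the transcription factor Cebpa (-2.98 ± 0.21), with a median of 0.08, a mean of -0.12 and -0.52 as median with library-size scaling, where 4 and 11 rose and fell. Of 19 genes of cholesterol efflux and lipid handling, 1 rose and 6 fell (1 and 6, 4 and 9 with the term, and 0 and 13 with library-size scaling), including the desaturase Scd2 (-3.36 ± 0.45).

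For other lists the called members depended on the fit and the scaling. The count that rose and the count that fell were 2 and 5 of 22 tricarboxylic acid cycle genes, 3 and 4 of 20 fatty acid oxidation genes, 2 and 3 of 23 cholesterol synthesis genes and 7 and 5 of 22 unfolded protein response genes. Adjusted over the list alone, these were 2 and 5, 3 and 4, 1 and 1, and 7 and 5. They were 4 and 7, 4 and 7, 4 and 11, and 7 and 5 with the replicate term. With library-size scaling they were 0 and 17, 1 and 14, 0 and 11, and 3 and 14. Of MHC class II and co-stimulation genes, 6 of 14 rose and 0 fell (6 and 0 adjusted over the list alone, 10 and 0 with the term), but 2 and 3 with library-size scaling, where the median of 0.95 was 0.35. Camera called this list with the term (adjusted p 0.00737) and not without it (0.0878), and not with an estimated correlation in either fit (with the term adjusted p = 0.477). Of oxidative phosphorylation genes 4 of 49 rose, of ribosomal protein genes 6 of 40, and of phagocytic and scavenger receptors 6 of 24 rose and 2 fell. Adjusted over the list alone, these were 3, 4, and 6 and 2. In the fit with the replicate term 16 of 49, 20 of 40 and 10 of 24 rose and 0, 0 and 6 fell. The medians of these last lists, 0.23, 0.25 and 0.20, were -0.37, -0.35 and -0.40 with library-size scaling, and the members that rose and fell were then 1 and 27, 0 and 21, and 4 and 11. Of the 12 mitochondrially encoded transcripts, 0 passed in edgeR's test (0 also with the replicate term). Their median was 0.05, and -0.56 with library-size scaling, where 0 and 7 rose and fell.

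Markers of other cells were mostly low. Of 7 tested dendritic cell markers 5 rose (6 adjusted over the list alone), among them the chemokine receptor Xcr1 (4.39 ± 1.02), whose adjusted p of 0.0109 was 0.0569 without control replicate 1, 0.0645 without control replicate 3 and 0.0624 without LPS replicate 1. The chemokine receptor Ccr7 held 0 and 14 reads and was at least 7.03-fold higher, with an adjusted p of 0.0132 in edgeR's test, 0.06 without control replicate 1 and 0.0619 without LPS replicate 1. Of 4 mast cell, basophil and eosinophil markers 1 rose, Hdc, the enzyme that makes histamine (7.61 ± 0.64). Of 6 stromal markers 1 rose, the growth factor receptor Pdgfrb (4.89 ± 0.70). The medians of these last lists, 0.01 and 0.09, were -0.59 and -0.51 with library-size scaling. Of lymphocyte markers only the kinase Lck (5.13 ± 0.65) and the receptor Il7r (-1.32 ± 0.20) could be tested. Of neutrophil and granulocyte precursor markers 2 could be tested and 0 passed in edgeR's test (2 with the replicate term, 1 in each direction). No erythroid marker held enough reads to be tested.

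In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 2663 genes rose and 2279 fell after LPS, 1783 and 1454 of them at least 2-fold. Adding the replicate term gave 3453 that rose and 3121 that fell. Without LPS replicate 3, 1397 genes fell. Camera called 10 of the 24 lists it could test. Cytokines (adjusted p = 0.00676 with an estimated correlation) and chemokines (0.0105) held with an estimated correlation, but neither did with the replicate term also in the fit (adjusted p = 0.0556 and 0.0879). The other 8 did not hold with an estimated correlation, with adjusted p between 0.192 (NF-kB subunits and effectors) and 0.733 (cell cycle). The called direction depended on scaling. With library size alone the median log2 fold change of all genes was -0.615 and 21.2% of calls were increases, against 53.9% with TMM. With upper-quartile factors these were -0.278 and 36.6%. In IL-4 then LPS against IL-4 alone the same 2 scalings gave -0.557 and -0.284, with 22.5% and 36% increases against 52.8%.

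IL-4 against control asked what 24 h of IL-4 changed in cells at rest. Retnla, Chil3 and Mgl2, transcripts of alternative activation, the macrophage state associated with IL-4, rose. Retnla, a secreted protein (ENSMUSG00000061100, chromosome 16, 48842551 to 48844461), held 0 reads in control and 547 after IL-4 (24.6 ± 1.61 CPM, n = 2), at least 178-fold higher. Chil3, a chitinase-like protein (ENSMUSG00000040809, chromosome 3, 106147554 to 106167564), rose from 2.10 ± 0.586 CPM to 109 ± 33.5 CPM, and the lectin gene Mgl2 (chromosome 11, 70130329 to 70137550) from 1.55 ± 0.376 CPM to 83.7 ± 39.5 CPM. Itgax, which encodes the integrin CD11c (ENSMUSG00000030789, chromosome 7, 128129547 to 128150657), rose from 111 ± 3.602 CPM to 446 ± 12.01 CPM. Cd5l, a secreted macrophage protein (ENSMUSG00000015854, chromosome 3, 87357881 to 87371073), fell from 61.0 ± 1.10 CPM to 15.9 ± 0.462 CPM.

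These were among 7 genes that rose and 1 that fell in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The log2 fold changes were 5.67 ± 0.33 for Chil3 (SE, adjusted p 0.00229), 5.73 ± 0.55 for Mgl2 (0.0128), 2.01 ± 0.15 for Itgax (0.00534) and -1.94 ± 0.17 for Cd5l (0.00748). Retnla had an adjusted p of 0.00534. Rnase2a, a ribonuclease of the eosinophil-associated family, held 0 and 321 reads and was at least 104-fold higher (0.00656). Dcstamp, a transmembrane protein of cell fusion, rose by 3.18 ± 0.28 (0.00748), and the small GTPase gene Rhoc, chosen after its values were seen, by 1.34 ± 0.15 (0.039). All 8 moved in the same direction in both replicate numbers. Chil3, Retnla and Rnase2a kept their calls whichever library was left out. Without control replicate 1 the adjusted p was 0.164 for Mgl2, 0.0633 for Itgax and 0.0633 for Cd5l, and 4 genes rose and 0 fell. Without control replicate 3 it was 0.156 for Mgl2, 0.0742 for Itgax, 0.0578 for Cd5l and 0.0578 for Dcstamp, and 3 genes rose. Cd5l lost its call without IL-4 replicate 1 (0.0866) or 3 (0.0753), where 0 and 2 genes fell. Rhoc lost its call without any 1 of the 8 libraries, with an adjusted p of 0.0906 without LPS replicate 3 at the least and 0.483 without control replicate 1 at the most. Fitting the 2 groups alone gave 0.0653 for Dcstamp and 0.142 for Rhoc.

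The fit with the replicate term raised these counts, and 183 genes rose and 105 fell, 79 and 45 of them at least 2-fold. An unadjusted p under 0.05 was found for 892 genes without the term, against 612 expected by chance, and DESeq2 called 65 genes higher and 45 lower. Further genes that passed with the term were Ccl22, a chemokine for T cells (log2 fold change 3.52 ± 0.43, adjusted p 0.00495), the transcription factor Egr2 (1.56 ± 0.18, 0.00392), Mrc1 (1.27 ± 0.14, 0.00369) and Arg1, arginase 1. Arg1 held 1 read in control and 53 after IL-4, a ratio of 51.7 (95% counting interval 8.88 to 2078), with adjusted p-values of 0.363 and, with the term, 0.0183. Genes that fell with the term were Cd14 (-1.34 ± 0.14), Il1b (-2.77 ± 0.50), Cx3cr1 (-2.50 ± 0.24), the inhibitory receptor gene Pilra (-2.11 ± 0.32), Ms4a6b (-1.98 ± 0.24) and Hpgd, which degrades prostaglandins (-2.56 ± 0.46). Tnf (0.15 ± 0.87), Nos2 (-0.86 ± 0.42), Cxcl10 (-0.01 ± 0.77), Tlr4 (-0.41 ± 0.19), Il4ra (-0.28 ± 0.61) and Il10 (-0.80 ± 1.83) passed in neither fit. The sign of Tnf turned without control replicate 1 (-0.63) or IL-4 replicate 3 (-1.49), and that of Cxcl10 without control replicate 3 (1.38) or IL-4 replicate 1 (0.70). Il12b held 1 and 4 reads, a ratio of 3.90 (95% counting interval 0.386 to 192), and Il6 and Ifnb1 held at most 2 reads in either group.

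**Figure D1:**
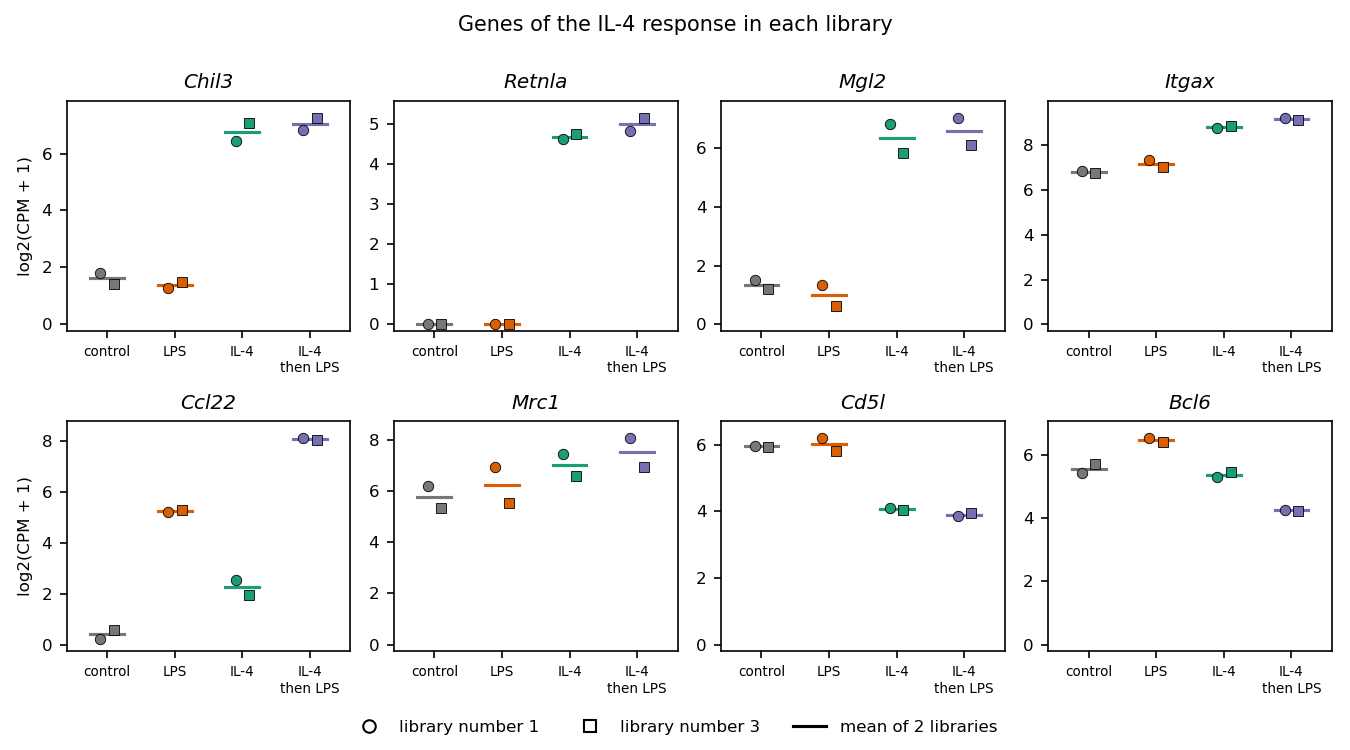
Level of 8 genes in each library, as log2 of CPM plus 1 on the vertical axis, for the groups control, LPS, IL-4 and IL-4 then LPS; circles are replicate 1, squares replicate 3 and lines the mean of the 2 libraries. Retnla, Chil3, Mgl2 and Itgax were higher and Cd5l lower with IL-4 in both replicate numbers, with and without LPS.

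Of 27 tested IL-4 and alternative activation genes, 3 rose and 0 fell at rest (13 and 0 adjusted over the list alone, 13 and 0 with the replicate term), with a median of 1.35 and of 1.26 with genes at the read floor set to it. Camera gave an adjusted p of 1.91e-44, and adjusted p = 0.017 with an estimated correlation. It was the list whose call held with an estimated correlation, of 16 called. Of 14 MHC class II and co-stimulation genes, 0 passed (7 higher and 2 lower adjusted over the list alone, 6 and 2 with the term). With the term the class II regulator Ciita (1.26 ± 0.13), the chaperone H2-DMb1 (1.10 ± 0.11) and the invariant chain Cd74 (0.95 ± 0.14) rose, and the co-stimulatory Cd86 (-1.66 ± 0.19) and Icosl (-1.32 ± 0.16) fell. Of 24 phagocytic and scavenger receptors, Itgax rose and Cd5l fell (2 and 5 adjusted over the list alone, 4 and 6 with the term, among them Cd36 at 0.95 ± 0.10 and Fcgr1 at -1.18 ± 0.14). Of 19 lipid handling genes, 3 were higher and 1 lower adjusted over the list alone and with the term, including Scd1 (1.47 ± 0.14). Of 18 cytokines, 1 was lower adjusted over the list alone, and with the term Il1b and Ebi3 (-1.06 ± 0.21) fell. Of these 18 cytokines 7 held at most 3 reads in control or in IL-4 cells, so the list's result here depends partly on few reads. Of 29 pattern recognition genes 2 were lower adjusted over the list alone, and with the term Tlr9 (-1.46 ± 0.24) was among 3 that fell and 1 rose. Of 49 oxidative phosphorylation genes, 48 had a positive fold change (median 0.29) and with the term 6 rose, including Cox8a (0.85 ± 0.16) and Cox5b (0.76 ± 0.12).

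At the preset correlation camera called higher the lists of oxidative phosphorylation (adjusted p 6.16e-12), cell cycle (3.82e-05), fatty acid oxidation (0.00129), unfolded protein response (0.00129), cholesterol synthesis (0.00508), MHC class II (0.00627), ribosomal proteins (0.0102), tricarboxylic acid cycle (0.0136) and lipid handling (0.0199). It called lower those of the interferon response (3.4e-06), cytokines (0.000711), pattern recognition (0.00129), macrophage identity (0.00129), phagocytic receptors (0.00627) and NF-kB genes (0.0238). With an estimated correlation the adjusted p of these 15 lists lay between adjusted p = 0.178 (cytokines) and 0.528. Oxidative phosphorylation and cytokines kept their preset-correlation calls without each library. Without control replicate 1 the adjusted p was 0.264 for the tricarboxylic acid cycle, 0.515 for cholesterol synthesis and 0.278 for ribosomal proteins. Without control replicate 3 it was 0.146 for lipid handling, 0.201 for cell cycle and 0.12 for class II, and the interferon (0.866) and NF-kB (0.976) lists turned upward. Without IL-4 replicate 1 it was 0.342 for pattern recognition, 0.901 for cell cycle, 0.115 for phagocytic receptors and 0.0875 for macrophage identity, and the interferon (0.718) and NF-kB (0.269) lists again turned upward. Without IL-4 replicate 3 it was 0.153 for both the tricarboxylic acid cycle and ribosomal proteins, 0.0642 for fatty acid oxidation, 0.103 for cholesterol synthesis, 0.0738 for lipid handling, 0.455 for class II and 0.264 for the unfolded protein response, and 10 lists were called.

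**Figure D2:**
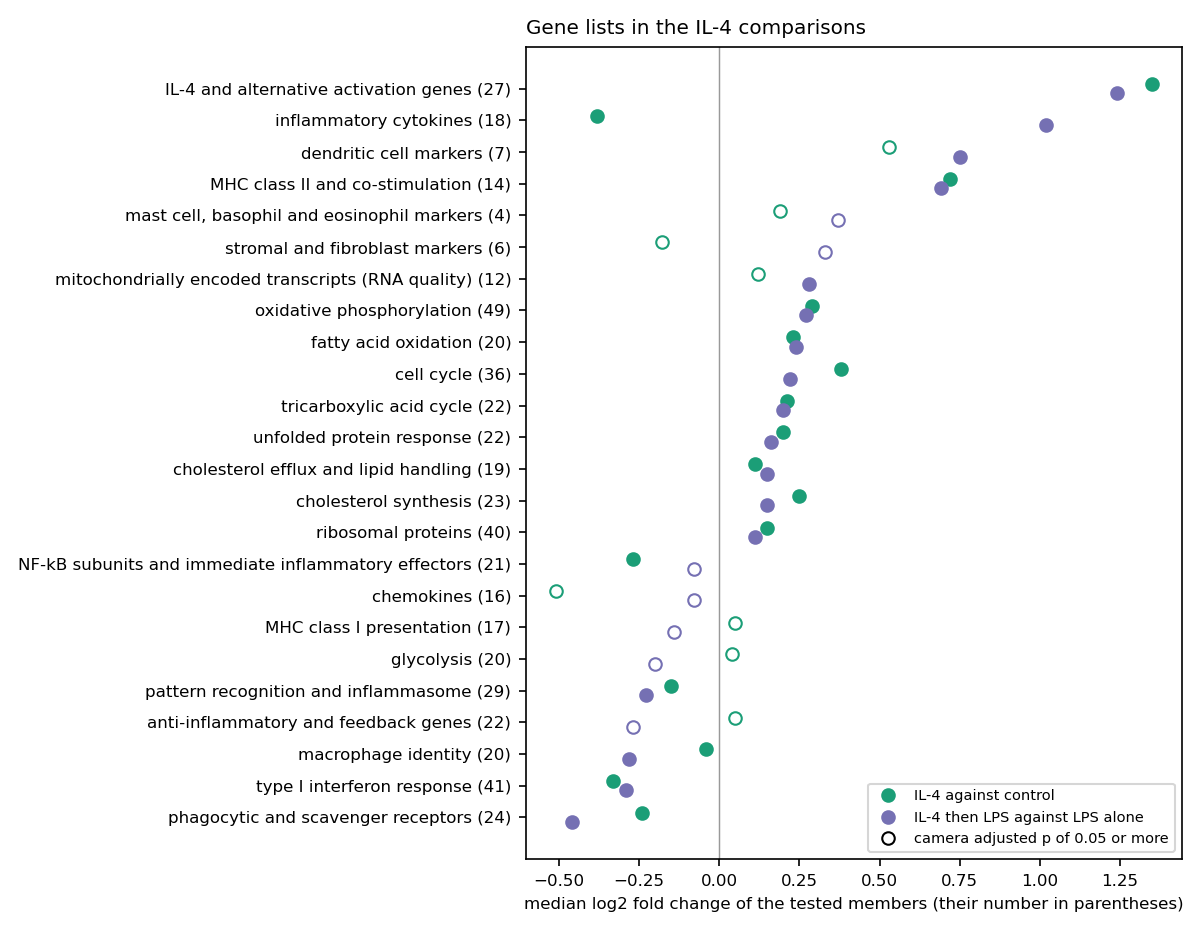
Median log2 fold change of 24 gene lists for IL-4 against control and for IL-4 then LPS against LPS alone; each point is a list and filled points have a camera adjusted p under 0.05 at the preset correlation. The IL-4 list has the largest medians, 1.35 and 1.24, and the cytokine list stands at -0.38 at rest and 1.02 after LPS.

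IL-4 then LPS against LPS alone asked whether earlier IL-4 changed the state that cells reached after LPS, the question named in the title of the series. Retnla, Chil3 and Mgl2 were again higher in cells that had received IL-4. Retnla held 0 reads after LPS alone and 456 after IL-4 then LPS (31.1 ± 5.20 CPM, n = 2), at least 150.1-fold higher. Chil3 was at 1.60 ± 0.28 CPM and 132 ± 29.2 CPM, a log2 fold change of 6.36 ± 0.36 (SE), and Mgl2 at 1.05 ± 0.698 CPM and 98.7 ± 44.0 CPM. The chemokine Ccl22 (ENSMUSG00000031779, chromosome 8, 94745590 to 94751699) rose from 37.0 ± 1.23 CPM to 271 ± 11.8 CPM. Bcl6, a transcriptional repressor (ENSMUSG00000022508, chromosome 16, 23965052 to 23988852), fell from 88.0 ± 6.22 CPM to 18.1 ± 0.23 CPM.

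In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 6 genes rose and 2 fell. Adjusted p-values were 0.00179 for Chil3, 0.00346 for Retnla, 0.00907 for Mgl2 (log2 fold change 6.54 ± 0.61) and 0.00489 for Rnase2a, which held 0 and 258 reads and was at least 84.9-fold higher. The same value of 0.00346 was found for Ccl22 (2.88 ± 0.22), Itgax (2.001 ± 0.15), Bcl6 (-2.28 ± 0.16) and Cd5l (-2.20 ± 0.17). Retnla, Rnase2a, Chil3, Itgax and Bcl6 kept their calls whichever library was left out. Mgl2 lost its call without LPS replicate 1 (0.101) or 3 (0.0922), Ccl22 without LPS replicate 1 (0.0599) and Cd5l without IL-4 then LPS replicate 1 (0.0593), where 1 gene fell. Fitting the 2 groups alone gave 0.0506 for Rnase2a, Mgl2 and Itgax and 0.0677 for Cd5l, with 4 genes higher and 1 lower. With the replicate term 132 genes rose and 149 fell, 64 and 53 of them at least 2-fold. An unadjusted p under 0.05 was found for 1040 genes, against 612 expected by chance, and DESeq2 called 61 higher and 58 lower.

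Several inflammatory cytokines were higher after IL-4 then LPS in both replicate numbers, without passing in the fit without the replicate term. Il1b was at 1187 ± 238 CPM after LPS and 2581 ± 1152 CPM after IL-4 then LPS, and Il6 at 485 ± 106 CPM and 995 ± 42.9 CPM. With the term, rises were called for Il1a (1.48 ± 0.17, adjusted p 0.00484), Il1b (1.06 ± 0.17, 0.0159), Il6 (1.05 ± 0.16, 0.0144), Il12a (1.46 ± 0.16, 0.00808), Il12b (0.68 ± 0.10, 0.0146) and Il23a, the specific subunit of interleukin 23 (2.71 ± 0.38, 0.0191). The same genes had adjusted p-values of 0.294, 0.442, 0.312, 0.526, 0.774 and 0.484 without the term. Il12b was at -0.10 without IL-4 then LPS replicate 3. Ebi3, a subunit shared by cytokines of the IL-12 family, was lower (-1.39 ± 0.19, 0.00944), and so was Il10 (-2.05 ± 0.39, 0.034), with 0.112 and 0.52 without the term. Csf2, a growth factor for myeloid cells, held 1 read after LPS and 37 after IL-4 then LPS, a ratio of 36.5 (95% counting interval 6.16 to 1482), and passed in neither fit. Tnf (0.37 ± 0.84, adjusted p 0.942), Nos2 (0.21 ± 0.22, 0.843), Cxcl10 (-0.34 ± 0.72, 0.936), Ifnb1 (0.07 ± 0.73, 0.991), Tlr4 (-0.03 ± 0.19, 0.982) and Il4ra (-0.98 ± 0.62, 0.723) passed in neither fit. Their signs turned without LPS replicate 1 for Tnf (-0.08), Tlr4 (0.13) and Il4ra (0.41), without LPS replicate 3 for Nos2 (-0.02) and Ifnb1 (-0.33), without IL-4 then LPS replicate 1 for Ifnb1 (-0.97) and without replicate 3 of that group for Tlr4 (0.21). Ifnb1 was at -0.02 with the term, and Tlr4 at 0.04 with library-size scaling.

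**Figure D3:**
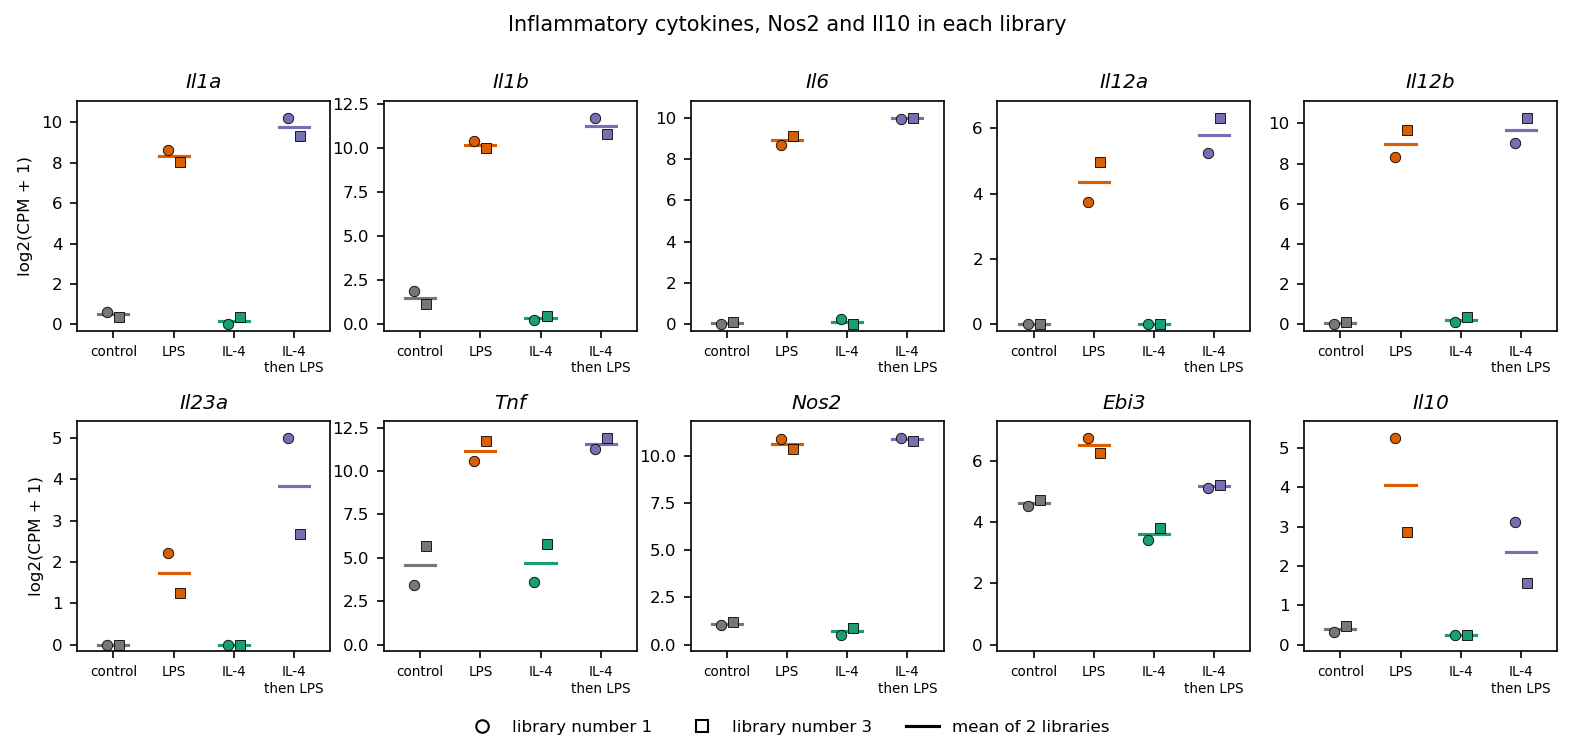
Level of 10 cytokine and effector genes in each library, as log2 of CPM plus 1 on the vertical axis, for the groups control, LPS, IL-4 and IL-4 then LPS; circles are replicate 1, squares replicate 3 and lines the mean of the 2 libraries. Il1a, Il1b, Il6, Il12a and Il23a were higher and Ebi3 and Il10 lower after IL-4 then LPS than after LPS alone in both replicate numbers, while Tnf and Nos2 passed in neither fit.

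Of 18 tested cytokines, 0 passed in edgeR's test over all genes, 6 were higher and 1 lower adjusted over the list alone, and 8 rose and 1 fell with the replicate term. The median log2 fold change was 1.02, also with genes at the read floor set to it. Camera gave an adjusted p of 5.8e-07, and adjusted p = 0.0518 with an estimated correlation. Of 27 IL-4 and alternative activation genes 4 rose and 0 fell (16 and 0 adjusted over the list alone, 12 and 0 with the term), with a median of 1.24. They included the T cell chemokine Ccl17 (3.33 ± 0.42 with the term, adjusted p 0.00678) and Mrc1 (1.28 ± 0.14, 0.0043). Arg1 held 0 and 51 reads, at least 16.8-fold higher, with an adjusted p of 0.284 and of 0.0144 with the term. The list's adjusted p in camera was 9.21e-51, with adjusted p = 0.0128 with an estimated correlation. Of 16 chemokines 0 passed over all genes and 0 adjusted over the list alone. With the term the neutrophil chemokines Cxcl1 (1.07 ± 0.14) and Cxcl3 (1.62 ± 0.25) and the monocyte chemokine Ccl2 (1.10 ± 0.18) were among 4 that rose, and Cxcl11 fell (-1.77 ± 0.30). The chemokine median was -0.08, the mean 0.10, and camera's direction upward without a call (adjusted p 0.132). Of 24 phagocytic and scavenger receptors Itgax rose and Cd5l fell (3 and 8 adjusted over the list alone, 4 and 7 with the term), with Cd36 at 0.99 ± 0.11 and Fcgr1 at -1.49 ± 0.13. Of 20 macrophage identity genes 5 were lower adjusted over the list alone and 4 with the term, including the transcription factor Maf (-1.03 ± 0.14) and the co-receptor Cd14 (-0.85 ± 0.14).

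Of 14 MHC class II and co-stimulation genes 4 were higher adjusted over the list alone, and with the term 6 rose and 1 fell, including Cd74 (0.85 ± 0.14) and Ciita (0.85 ± 0.13). Of 22 unfolded protein response genes 4 were higher adjusted over the list alone and 3 rose with the term, including the chaperones Sdf2l1 (0.88 ± 0.14) and Calr (0.62 ± 0.10). Of 22 tricarboxylic acid cycle genes 2 were higher and 1 lower adjusted over the list alone, and with the term Idh2 (0.75 ± 0.14) and Aco1 (0.52 ± 0.10) rose. Of 19 lipid handling genes 4 were higher and 1 lower adjusted over the list alone, and 3 and 1 with the term, among them Scd1 (1.26 ± 0.14 with the term). Of the NF-kB effectors Ptgs2 (0.71 ± 0.11) was among 2 that rose with the term, and of 20 glycolysis genes Pfkfb3 (-1.24 ± 0.23) was among 2 that fell. Other genes called with the term were Tmem176b (-1.93 ± 0.15), Ms4a6b (-2.41 ± 0.23), Gpr162 (-1.96 ± 0.34) and Dcstamp (2.11 ± 0.27).

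Camera called 17 lists at the preset correlation, and of these the IL-4 list held with an estimated correlation. Called higher besides the IL-4 list and cytokines were oxidative phosphorylation (adjusted p 7.45e-11), tricarboxylic acid cycle (0.00021), class II (0.000215), dendritic cell markers (0.000429), cell cycle and unfolded protein response (0.00091 each), mitochondrial transcripts (0.00503), cholesterol synthesis (0.00758), fatty acid oxidation (0.0096), lipid handling (0.0198) and ribosomal proteins (0.0296). Called lower were macrophage identity (0.000215), phagocytic receptors (0.000333), the interferon response (0.00091) and pattern recognition (0.00503). With an estimated correlation these 15 lists had values between adjusted p = 0.184 (dendritic markers) and 0.563. Feedback genes were called lower with the replicate term (adjusted p 0.0277, 0.0957 without it), and not with an estimated correlation in that fit (adjusted p = 0.546). Without LPS replicate 1 the adjusted p was 0.0583 for lipid handling and mitochondrial transcripts and 0.286 for ribosomal proteins, and cholesterol synthesis turned downward (0.345). Without LPS replicate 3 it was 0.118 for pattern recognition, 0.0833 for lipid handling and 0.152 for cell cycle. Without IL-4 then LPS replicate 1 it was 0.0768 for pattern recognition and 0.501 for cell cycle. Without replicate 3 of that group it was 0.203 for fatty acid oxidation, 0.612 for cholesterol synthesis, 0.0815 for class II, 0.0978 for the unfolded protein response and 0.785 for ribosomal proteins.

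Among 1857 LPS-induced genes, 1 was called higher after prior IL-4 and 0 lower in edgeR's test, and that gene was Ccl22. The median log2 fold change of these genes was -0.153, with 33% above 0, against -0.012 for the other genes. With the replicate term, 44 of 1899 LPS-induced genes were higher and 50 lower. DESeq2 called 20 higher and 17 lower. Without LPS replicate 1 the count was 0 higher and 0 lower, and without control replicate 1 it was 2 higher and 1 lower. Without control replicate 3, either IL-4 replicate or either replicate of IL-4 then LPS it was 2 higher and 0 lower. Among 1780 LPS-reduced genes 0 were called in either direction, with 10 higher and 22 lower of 1899 with the term and a median of -0.045.

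IL-4 then LPS against IL-4 alone gave the LPS response of cells that had been exposed to IL-4. Inflammatory genes rose in these cells too. Il1b rose from 0.271 ± 0.13 CPM to 2581 ± 1152 CPM (n = 2, log2 fold change 13.15 ± 0.65, SE) and Nos2 from 0.631 ± 0.261 CPM to 1883 ± 147 CPM (11.51 ± 0.37). Edn1 held 0 reads with IL-4 alone and was at least 2684-fold higher. Cnr2 fell from 85.7 ± 0.431 CPM to 0.535 ± 0.344 CPM (-7.25 ± 0.35).

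Il6 held 2 reads with IL-4 alone and was 11080-fold (95% counting interval 3066 to 91480) higher after LPS, Il1a held 3 reads and was 6780-fold (95% counting interval 2319 to 32880) higher, and the protease gene Adamts4 held 0 reads and was at least 499.7-fold higher. Il12b (12.17 ± 0.92), Tnf (6.58 ± 1.07), Cxcl10 (8.59 ± 1.01) and Cd14 (2.98 ± 0.20) rose, and Ifnb1 held 0 and 57 reads, at least 29.0-fold higher. Il10 rose by 4.63 ± 1.29 (adjusted p 0.0239), and its adjusted p was 0.102 without IL-4 replicate 1, 0.0926 without IL-4 replicate 3 and 0.138 without IL-4 then LPS replicate 1. Plekhg3 was 127-fold (95% counting interval 43.2 to 617) lower, the angiogenesis regulator Vash2 120.5-fold (95% counting interval 21.4 to 4786) lower and Cx3cr1 78.0-fold (95% counting interval 13.7 to 3104) lower. Foxred2 fell by 5.66 on the log2 scale. Retnla (0.34 ± 0.21, adjusted p 0.259), Chil3 (0.28 ± 0.25, 0.402), Arg1 (0.59 ± 0.81, 0.597), Tlr4 (0.20 ± 0.19, 0.44) and Il4ra (0.78 ± 0.62, 0.357) passed in neither fit. Mrc1 (0.55 ± 0.55, 0.468) passed with the replicate term (0.0142). With library-size scaling Retnla was at -0.19, Chil3 at -0.24 and Tlr4 at -0.32, and Tlr4 at -0.05 with upper-quartile factors. Without IL-4 then LPS replicate 1, Arg1 was at -0.60, Mrc1 at -0.12 and Tlr4 at -0.09.

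In edgeR's test 2537 genes rose and 2271 fell, 1665 and 1470 of them at least 2-fold, and with the replicate term 3182 rose and 3151 fell. Without IL-4 replicate 1, 1315 genes fell, without IL-4 replicate 3, 1505, and without IL-4 then LPS replicate 3, 1329. All 41 interferon response genes rose (median 5), with 18 of 18 cytokines (median 7.38, and 6.80 with genes at the read floor set to it), 15 of 16 chemokines, 20 of 21 NF-kB genes and 16 of 17 MHC class I genes. Adjusted over the list alone these counts were 41, 18, 15, 21 and 16. Of 22 feedback genes 18 rose and 1 fell, of 29 pattern recognition genes 19 rose and 5 fell, and of 36 cell cycle genes 1 rose and 17 fell. Adjusted over the list alone these were 18 and 1, 20 and 6, and 2 and 19. Of the cell cycle genes 4 rose and 27 fell with the replicate term. Camera called 11 lists. Cytokines (adjusted p = 0.00394) and chemokines (adjusted p = 0.0284) held with an estimated correlation. Cytokines held with the replicate term also in the fit (adjusted p = 0.0164) and chemokines did not (adjusted p = 0.0806). The other 9 did not hold with an estimated correlation in the fit without the term, with adjusted p between 0.112 (pattern recognition) and 0.744 (cell cycle). Of these, class II also lost its preset-correlation call without IL-4 replicate 1 (0.0801) or IL-4 then LPS replicate 3 (0.0833), and dendritic markers without IL-4 then LPS replicate 1 (0.0627) or with the replicate term (0.0746).

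The difference of the LPS responses with and without prior IL-4 was tested as an interaction. Il1b had the larger response after IL-4 by 3.92 ± 0.82 on the log2 scale (SE, n = 2 per group), positive in both replicate numbers, without passing (adjusted p 1, and 0.148 with the replicate term). Cxcl3 was at 4.04 ± 1.41, Il1a at 3.04 ± 1.24 and Cxcl1 at 2.71 ± 1.298, and Bcl6 at -2.08 ± 0.21. With IL-4 alone Il1b held 6 reads over both libraries, Cxcl1 5, Il1a 3 and Cxcl3 2, so these 4 values depend on few reads. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 0 genes differed in either direction, with 322 genes at an unadjusted p under 0.05 where chance gives 612. With the replicate term 789 genes had such a p. A count below chance means that the fit without the term may call too few genes here, so 0 calls do not show equal responses. With the replicate term Bcl6 passed (adjusted p 0.0259, 0.159 without the term). DESeq2 called 4 genes higher and 1 lower, and DESeq2 with the replicate block 11 and 20.

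Other followed genes lay at 1.07 ± 0.47 (Nos2), 0.68 ± 0.51 (Chil3), 0.49 ± 0.26 (Cd14), 0.37 ± 0.27 (Tlr4), 0.22 ± 1.21 (Tnf), -0.01 ± 0.78 (Mrc1), -0.33 ± 1.05 (Cxcl10), -0.70 ± 0.87 (Il4ra), -1.38 ± 2.27 (Il10) and -1.73 ± 0.53 (Egr2), none with a call in either fit. Il12b was at -1.03 ± 2.26 on 1 control read, while its differences within replicates 1 and 3 were 0.22 and 0.02, so its direction is uncertain, and it passed in neither fit. Signs turned without control replicate 1 for Cxcl10 (0.44), without IL-4 replicate 3 for Cxcl10 (1.33) and without LPS replicate 1 for Tnf (-0.23), Il10 (0.43), Il4ra (0.69) and Mrc1 (0.86). They also turned without control replicate 3 for Tnf (-1.32) and Mrc1 (0.42), without IL-4 replicate 1 for Tnf (-0.47) and Mrc1 (0.51), and without IL-4 then LPS replicate 3 for Tnf (-0.15) and Mrc1 (0.45). Of 18 cytokines 3 were higher and 0 lower adjusted over the list alone, with a median of 1.24 and of 1.32 with genes at the read floor set to it. At that floor in at least 1 group were 7 of the 18, and their differences depend mainly on the levels after LPS. Camera gave the cytokines an adjusted p of 9.43e-08, and adjusted p = 0.0747 with an estimated correlation. The 16 chemokines had a median of 0.35, and of 0.17 at the floor, with 0 called over all genes or adjusted over the list alone and a camera adjusted p of 0.014 (adjusted p = 0.725 with an estimated correlation). Their list lost its call without control replicate 3 (0.536) or IL-4 replicate 1 (0.103). Adding the replicate term gave 4 called lists, cytokines (adjusted p 1.63e-06) and chemokines (0.0108) higher and MHC class I genes (0.00248) and feedback genes (0.0395) lower. None of these held with an estimated correlation in that fit, with adjusted p = 0.733 for cytokines and 0.982 for the others. Without replicates 1 and 3 the called lists numbered 7 and 5 for control, 4 and 6 for LPS, 5 and 8 for IL-4, and 5 and 3 for IL-4 then LPS. No other list passed without the term, the lowest adjusted p being 0.117 for feedback genes. For the IL-4 list the median was -0.02, the mean 0.07 and camera's direction downward (adjusted p 0.964).

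Across the 12234 tested genes, the IL-4 effect at rest and the IL-4 effect after LPS correlated with Pearson's r = 0.415 and Spearman's rho = 0.38, and r was 0.578 over the 9885 genes with a mean log2 CPM of at least 2. The LPS effects without and with IL-4 correlated with r = 0.927 and rho = 0.91. In the fit without the replicate term 5 genes were higher in both IL-4 comparisons, namely Retnla, Rnase2a, Mgl2, Chil3 and Itgax, and 1 was lower in both, Cd5l. With the term 75 genes were higher in both, where independent lists of that size would share 1.97, and 47 were lower in both, where 1.28 would be shared. Calls in opposite directions were found for 1 gene, Il1b, a call at rest without a call after LPS for 165, and the reverse for 158.

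**Figure D4:**
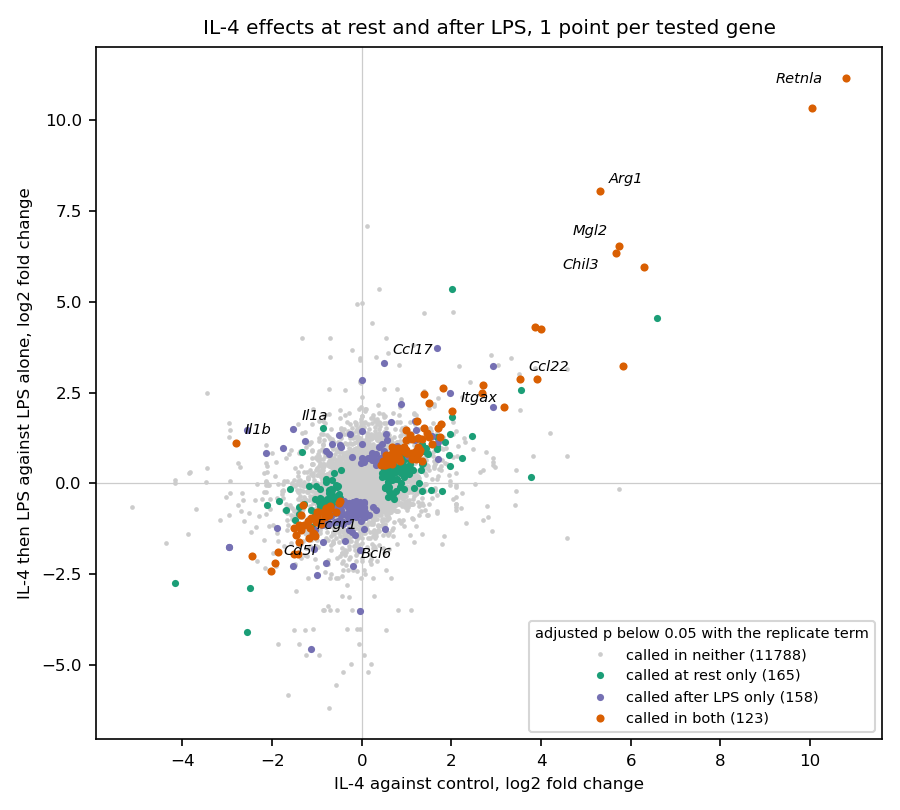
Log2 fold change of IL-4 against control on the horizontal axis and of IL-4 then LPS against LPS alone on the vertical axis; each point is 1 of the 12234 tested genes, coloured by its call with the replicate term, and values of genes without reads in a group depend on the prior count. Of the coloured genes 123 were called in both comparisons, 165 at rest alone and 158 after LPS alone.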

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

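The tests of scaling, of a higher level of all induced genes after LPS and of depth were chosen only after the result was seen.

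Some genes were flagged for an IL-4 effect that differed between rest and LPS, by the interaction test or by sign alone. Bcl6 differed by -2.08 on the log2 scale in the interaction test with the replicate term (adjusted p 0.0259), and not without it (0.159). The IL-4 effect on Bcl6 was -0.14 and -0.26 at rest in replicates 1 and 3, and -2.33 and -2.21 after LPS. Other genes stood out because both replicate numbers moved one way at rest and the opposite way after LPS, and for each of these the interaction test did not pass in either fit. Il1b differed by 3.92 (with IL-4 effects of -2.87 and -1.27 at rest and 1.32 and 0.79 after LPS). Il1a differed by 3.04, Cxcl3 by 4.04 and Cxcl1 by 2.71. With IL-4 alone Il1b held 6 reads over both libraries, Il1a 3, Cxcl3 2 and Cxcl1 5, so these values rest on few reads. Nos2 differed by 1.07 and Ptgs2 by 0.94. Some of these moves were close to no change. In replicate 3 the IL-4 effect at rest was -0.07 for Il1a and -0.02 for Ptgs2. In replicate 1 the effect after LPS was 0.05 for Nos2. Nos2 held 25 reads in control and 14 with IL-4 alone, and Ptgs2 26 and 23.

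The list tests of the same difference gave a median of 0.35 for chemokines, whose call ended with an estimated correlation (adjusted p 0.725), and of 1.24 for inflammatory cytokines (adjusted p 0.0747 with an estimated correlation).

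After LPS, camera called the list of 18 tested inflammatory cytokines higher in cells with prior IL-4 at the preset correlation (median 1.02 on the log2 scale), but not with an estimated correlation (adjusted p 0.0518, and 0.116 with the replicate term), and 0 of the 18 genes passed over all genes without the replicate term. Scaling moves all genes of a library alike, and it was argued against. The list median was 1.01 with RLE factors, 1.05 with upper-quartile factors and 1.09 with library size. The median over all genes was -0.028 with TMM and 0.036 with library size. Of 10000 random lists matched on mean expression, 0% had a median as high (highest 0.279). That matching used the mean over all 8 libraries. Matched genes therefore need not share the cytokines' level after LPS, and these lists do not decide on sequencing depth. The totals argue against depth for this list. They were 8689368 and 9212153 counts after LPS and 7924932 and 9431852 after IL-4 then LPS. Neither group was thus the deeper one in both replicate numbers. Of the 18 members 1 lay at the read floor, and the median with it set to the floor was also 1.02. A higher level of all induced genes after LPS was argued against. The values compare levels after LPS and do not test the size of the LPS response itself. The 1857 LPS-induced genes had a median of -0.153 in this comparison, with 33% above 0. Of 10000 lists matched on the average LPS effect, 0% had a median as high as the cytokines (highest 0.769). For members near the top of the LPS response the nearest genes lie mostly below them. A higher level of the most induced genes alone was therefore not decided. A hypothesis that remains, found and tested on the same 8 libraries, is that prior IL-4 may raise the level after LPS of part of the cytokine genes, Il1a, Il1b, Il6, Il12a, Il12b and Il23a among them and Il10 and Ebi3 not, while a larger LPS response was called for none of these. At the preset correlation camera called 17 lists in this comparison, some higher and some lower. Dendritic cell markers (median 0.75) and mitochondrial transcripts (median 0.28, 12 of 12 positive) were among those called higher. With an estimated correlation neither held (camera adjusted p 0.184 and 0.212). Macrophage identity, phagocytic receptors, the interferon response and pattern recognition were called lower.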

How the results depend on the processing

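The fits named DESeq2 with replicate block and replicate block without X and Y genes, and the estimated correlation with replicate block, were chosen only after the result was seen. The 2 libraries per group limit what can be called, and the depth of 7924932 to 9431852 counts limits genes with few reads. RLE factors and the filter of at least 1 CPM in 2 libraries changed no call of a named gene and no count by more than 1.5 times. Of 178 results for named genes, the replicate block brought 58 calls, ended none and turned 1 sign, and DESeq2 brought 35. Part of these genes were named because the replicate block called them, so the number of calls it brought was partly fixed by that choice. Of 56 list calls, 50 ended with an estimated correlation, 1 with the replicate block and 53 with both. Where a result moved, the cause was not tested.

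Counts of genes higher and lower in IL-4 against control were 65 and 45 with DESeq2, 198 and 162 without the low-count filter, 183 and 105 with the replicate block, 213 and 185 with DESeq2 and the block, and 175 and 104 with the block without X and Y genes. In the same order, IL-4 then LPS against LPS alone gave 61 and 58, 172 and 225, 132 and 149, 172 and 244, and 129 and 139, and the compared groups alone gave 1 lower. The difference of responses gave 4 and 1, 16 and 37, 0 and 1, 11 and 20, and 0 and 1. LPS-induced genes higher and lower after prior IL-4 were 20 and 17, 64 and 81, 44 and 50, 49 and 89, and 43 and 47, and the compared groups alone gave 2 higher. With library size as the scaling, LPS against control gave 1547 and 5745 and IL-4 then LPS against IL-4 alone 1546 and 5321. With upper-quartile factors 3542 and 3426 genes were lower. The correlation of the IL-4 effects was 0.578 over genes with a mean log2 CPM of at least 2. The lists called numbered 2, 1, 1, 2 and 0 with an estimated correlation, in the order LPS against control, IL-4 against control, IL-4 then LPS against LPS alone, IL-4 then LPS against IL-4 alone and the difference, and 4 for the difference with the replicate block. With the estimated correlation and the replicate block they numbered 0, 1, 1, 1 and 0.

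Leaving out each library in turn, LPS against control gave 1829 to 2549 genes higher and 1397 to 2230 lower, IL-4 against control 3 to 7 and 0 to 2, IL-4 then LPS against LPS alone 4 to 9 and 1 to 3, and IL-4 then LPS against IL-4 alone 1801 to 2511 and 1315 to 2294. LPS-induced genes higher after prior IL-4 numbered 0 to 2 and those lower 0 to 1. Lists called numbered 10 to 17 in IL-4 against control and 3 to 8 in the difference. The adjusted p of the list NF-kB subunits and immediate inflammatory effectors in IL-4 against control ran from 2.25e-09 to 0.976, that of the list type I interferon response in IL-4 against control from 2.18e-25 to 0.866, and that of the list cholesterol synthesis in IL-4 then LPS against LPS alone from 1.01e-08 to 0.612, with a turn of direction in each. Log2 values of genes whose sign turned, none of them called without the replicate term, were as follows. The range of Mrc1 in LPS against control was -0.31 to 1.11. The range of Tnf in IL-4 against control was -1.49 to 1.71 and that of Cxcl10 in IL-4 against control was -1.64 to 1.38. The range of Il12b in IL-4 then LPS against LPS alone was -0.099 to 1.48, that of Tnf in IL-4 then LPS against LPS alone was -0.083 to 1.03 and that of Nos2 in IL-4 then LPS against LPS alone was -0.023 to 0.49. The range of Ifnb1 in IL-4 then LPS against LPS alone was -0.97 to 0.68, that of Tlr4 in IL-4 then LPS against LPS alone was -0.32 to 0.21 and that of Il4ra in IL-4 then LPS against LPS alone was -1.67 to 0.41. The range of Arg1 in IL-4 then LPS against IL-4 alone was -0.60 to 1.60, that of Mrc1 in IL-4 then LPS against IL-4 alone was -0.12 to 1.02 and that of Tlr4 in IL-4 then LPS against IL-4 alone was -0.089 to 0.45. The range of Il10 in difference of LPS responses with and without prior IL-4 was -2.67 to 0.43, that of Tnf in difference of LPS responses with and without prior IL-4 was -1.32 to 1.88 and that of Cxcl10 in difference of LPS responses with and without prior IL-4 was -1.69 to 1.33. The range of Il4ra in difference of LPS responses with and without prior IL-4 was -1.40 to 0.69 and that of Mrc1 in difference of LPS responses with and without prior IL-4 was -0.69 to 0.86.

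Signs also turned under other settings. With library size as the scaling, Mrc1 in LPS against control was at -0.034 and Mrc1 in the difference at 0.065. Tlr4 in IL-4 then LPS against LPS alone was at 0.035. In IL-4 then LPS against IL-4 alone Retnla was at -0.19, Chil3 at -0.24 and Tlr4 at -0.32, and Tlr4 at -0.046 with upper-quartile factors. Ifnb1 in IL-4 then LPS against LPS alone was at -0.02 with the replicate block, -0.06 with DESeq2 and the block and -0.018 with the block without X and Y genes. Mrc1 in the difference was at 0.032 and 0.012 in these last fits.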

Other observations

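The tests of the sex chromosomes, of sex beyond them and of dendritic cells were chosen only after the result was seen, and the test of other cell types was written before.

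Libraries numbered 1 and 3 differed in a way that was partly shared by all 4 groups. The replicate term was called for 1638 of 12234 genes in edgeR's quasi-likelihood test, 731 higher in number 3 and 907 higher in number 1, and 1576 of them lay outside the X and Y chromosomes. Cell cycle genes were higher in number 1 (26 of 36 called, 0 higher in number 3, median of number 3 minus number 1 -0.57 on the log2 scale). Of 23 cholesterol synthesis genes 12 were higher in number 3 and 0 in number 1 (median 0.47), and of 17 MHC class I genes 12 and 0 (median 0.45). Of 21 NF-kB subunits and effectors 9 were higher in number 3 and 1 in number 1 (median 0.49). Camera called these lists at the preset correlation, and with an estimated correlation each had an adjusted p of at least 0.492. The median of the 41 interferon response genes was 0.80 higher in number 3 in control and 0.86 higher in IL-4 cells, but -0.02 after LPS and 0.00 after IL-4 then LPS. These genes were lower after IL-4 than in control in camera's test, a call that ended with an estimated correlation (adjusted p = 0.528) and a direction that turned without control replicate 3 or IL-4 replicate 1.

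What the replicate numbers stand for stays open, but genes of the sex chromosomes alone were argued against, because deviations from the group means remained correlated without X and Y genes in all 6 pairs of groups (lowest r 0.28). Sex of the animals beyond the sex chromosomes cannot be told apart from batch or animal, because in each of the 4 groups 1 library has Xist reads and the other none. For cells of another type in the libraries of 1 number, 1 of 6 marker lists, that of neutrophils and granulocyte precursors, differed in the same direction in all 4 groups, by 2.09 to 3.55 times. This met the criterion set beforehand for such cells, a difference of 2-fold or more in the same direction in all 4 groups. Such cells cannot be told apart from a change of Mmp8 alone, because Mmp8 (59 to 627 reads) carried most of this sum. Without Mmp8, left out after the values were seen, the sum was higher in number 3 by 1.38 to 2.96 times, and of its other markers S100a8 held 9 to 40 reads per library, S100a9 0 to 12, 7 at most 4 and 5 none.

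Itgax, MHC class II genes and the chemokines Ccl17 and Ccl22 are also known from dendritic cells. With the replicate term, Itgax, Ccl22 and 6 of 14 class II and co-stimulation genes were higher after IL-4 at rest, 2 of the 14 were lower, Cd86 and Icosl, and Ccl17 was higher after IL-4 then LPS than after LPS alone. The summed level of 13 dendritic markers went from 3.81 and 3.46 CPM in control to 7.50 and 8.34 CPM after IL-4 in replicates 1 and 3, a rise of 1.14% and 1.41% of that of Itgax (1.19% and 1.33% without Ccl17), and from 22.5 and 16.2 CPM after LPS to 45.1 and 33.9 CPM after IL-4 then LPS, 5.12% and 4.21% (0.695% and 0.415% without Ccl17). At least 5% without Ccl17 was set as what dendritic cells among the cultured cells would need and under 1% for the whole list as what would exclude them. Both limits were set without a dendritic cell reference and are arbitrary. Neither was met, and dendritic cells cannot be told apart from a change in the macrophages. Ccl17 is itself among the genes to be explained, and the shares without it and Batf3 (0.185% and -0.0191% at rest, 0.239% and -0.102% after LPS), left out after the values were seen, were low, which does not exclude such cells because Ccl17 and Batf3 are markers that rose.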
